A study of Homo sapiens with 6 samples.

How the data were processed

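RNA was measured in 6 libraries from organoids grown from an induced pluripotent stem cell line derived from IMR90, an established human fibroblast line. Of these, 3 were control neural organoids and 3 were optic vesicle-containing brain organoids, called OVB organoids here. Per the labels' protocols the libraries were made from polyadenylated RNA with a TruSeq kit, and the growth protocol is worded alike for both kinds of organoid. The labels give no age at collection and do not say how many organoids went into a library. The library codes in the titles share a first part over all control libraries and another over all OVB libraries. That part is read here as a run code, though the labels do not say what it stands for. Run, so read, and group cannot be told apart. The alignments were named as sorted for the OVB libraries alone.

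The authors deposited whole-number read counts per gene for each library. Per the file headers the counts came from featureCounts 1.6.0 with primary alignments of read pairs, without a strand setting, on an hg19 annotation with Ensembl gene identifiers. Per the submitters' processing notes STAR, featureCounts, DESeq2 and hg19 were used. The versions of STAR and DESeq2 are not given in the sources used here. Since primary alignments of reads with several matches were counted, genes with near-identical copies are uncertain. Since strand was not used, reads of a gene and of an overlapping gene on the other strand cannot be told apart. The authors also deposited a table of 23840 genes with log2 fold changes, their standard errors, and p-values with adjusted p-values for this comparison. That table was used only for gene symbols and for a comparison of calls. Its 6 columns of per-sample values were not used.

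The count table held 63677 features, of which 41320 had at least 1 count. The 37 mitochondrial features and the 5904 features on patch, haplotype or unplaced sequences had 0 counts in all, so nothing can be said of mitochondrial transcripts. Symbols came from the authors' table for 23840 identifiers and from the reference name table for 29479 more, and 10358 had none. Coordinates are those of the count table in hg19, counted from 1.

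The main comparison used edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr, a robust quasi-likelihood fit, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a gene comes from this test unless another is named. Fold changes are OVB over control, and the standard error is the log2 fold change divided by the square root of F. CPM are read counts scaled to the TMM-adjusted library size. The 34 gene lists, with 664 genes in all, were fixed before the data were examined, as were the tests, most of the alternative settings and the rule for naming genes. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The HOX list had 3 tested members and the mitochondrially encoded list 0, so neither was tested. The list genes PECAM1 and HIST1H1A were not matched to a feature.

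Genes named are of 3 kinds. The first are the 6 largest rises and the 6 largest falls past the threshold with no overlap between the groups and a mean of at least 5 CPM in the higher group, leaving out symbols that start with LOC, LINC, RP with digits and a dash, AC or AL with digits, MIR, SNOR or RNU, symbols with -AS or ending in P and a digit, XIST, TSIX and Y-linked genes. The second are up to 3 members of each list past the threshold with the largest change and a mean of at least 1 CPM in the higher group. The third are 12 anchors named whatever their values. Some genes that the rule picks are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

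Counts were simulated for 21718 genes with the means and library sizes of this comparison. Of these genes, 100 were set to a 2-fold change and 100 to a 4-fold change. The test called 15% of the former and 56% of the latter, and 6.58% of its 76 calls were unchanged genes. Far more genes were called in the real comparison, which loosens the adjusted threshold, so these shares do not carry over to it. In 20 simulations of the list test, both moved lists were called in all 20, and a mean of 0.2 of 30 unmoved lists were called. Genes were drawn independently of each other there. The simulations thus say nothing of lists whose members vary together, such as the cell cycle list (estimated correlation between members 0.95).

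Library totals ran from 48166146 to 72019150 counts. Counting intervals are exact at 95% and cover counting error only. The libraries were compared by a chi-square over genes, and the lowest value for any pair was 24.7 per degree of freedom, so no library was counted as a repeat of another. The labels call the libraries replicates without saying what was repeated, so p-values measure the spread between these libraries. Alternatives were other scalings and filters, DESeq2 1.42.0, limma-voom, thinning to the smallest library, the replicate number as a block, and leaving out each library. For the lists they included camera with an estimated correlation and fry, a directional list test in limma. A correction for GC content and gene length, with and without the block, was added after seeing the data. GC content was taken from GENCODE transcript sequences matched by identifier, with no coordinates of that build used.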

Results

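Gene expression was measured by RNA sequencing in 3 libraries of control neural organoids and 3 of OVB organoids, brain organoids that carry optic vesicles. The comparison asks how the transcripts of OVB organoids differ from those of control neural organoids. Control libraries held 53690473, 55543269 and 72019150 counts, and OVB libraries held 48485278, 57987605 and 48166146.

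OVB organoids differed from control organoids in many genes, with higher levels of cortical neuron, pigment cell and choroid plexus genes and lower levels of cell cycle genes and most stem cell genes. Among 21718 tested genes, 4748 were higher and 4386 lower in OVB organoids, and 5914 of these changed at least 2-fold. The groups did not overlap in 9045 of the called genes, and over all tested genes they did not overlap in 57.4%, where chance gives 10%. The largest fall was in LIN28A, an RNA-binding protein of early embryonic cells (ENSG00000131914, chromosome 1, 26737269 to 26756213), at 70.3 ± 11.1 CPM in control and 0.502 ± 0.326 CPM in OVB organoids (SD, n = 3 each). Its log2 fold change was -7.12 with a standard error of 0.47 and an adjusted p of 0.00114. The transcription factor LHX5 fell by 4.72 on the log2 scale (SE 0.22, adjusted p = 0.000559), though an antisense feature shares its exons and held 35.9% as many counts. GPR149, POMC and SALL4 fell by 4.62, 4.46 and 4.18, and DPPA4 by 4.29.

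The largest rises were in genes close to absent from control organoids, so their folds are imprecise. KRT5, a keratin of basal epithelium (ENSG00000186081, chromosome 12, 52908359 to 52914471), had 1 control count and 3663 OVB counts, a ratio of 3296 with a counting interval of 591 to 130200. ABCC3 had 3 and 2046 counts and USH1C 3 and 1205, ratios of 614 (interval 210 to 2978) and 361 (interval 123 to 1755). SULT1E1 rose by 9.21 on the log2 scale (SE 2.09) and the cytokine gene IL33 by 9.09 (SE 1.15). The 3 OVB libraries were unequal here, since KRT5 stood at 3.82, 49.9 and 0.942 CPM. The call of KRT5 was lost without control replicate 1 (adjusted p = 0.064). Those of SULT1E1 and ABCC3 were lost without any 1 of the control libraries (adjusted p from 0.0555 to 0.0641 and from 0.0521 to 0.0613). That of DPPA4 was lost without any 1 control library or OVB replicate 1 (adjusted p from 0.0675 to 0.0722).

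**Figure D1:**
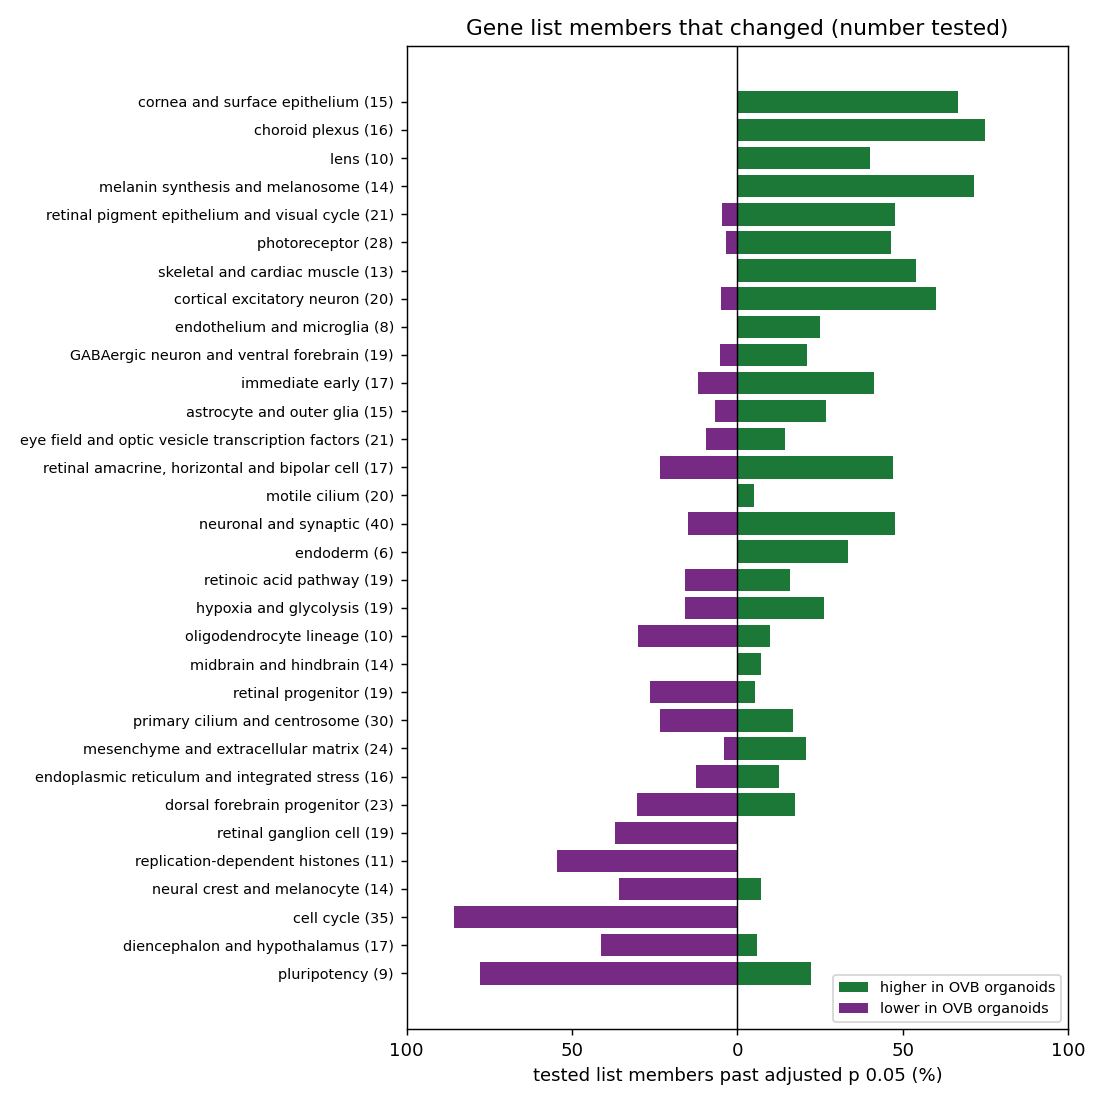
Each bar gives the percentage of tested members of a gene list that were higher (right, green) or lower (left, purple) in OVB organoids at an adjusted p below 0.05, with the number tested in brackets. Of 35 cell cycle genes 30 were lower, and of 16 choroid plexus genes 12 were higher.

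Pigment cell genes were higher in OVB organoids. In the melanin list 10 of 14 tested members rose and 0 fell, or 12 and 0 adjusted over the list alone, and the list was called higher (camera adjusted p = 0.00588, adjusted p = 0.814 with an estimated correlation). TYR, the rate-limiting enzyme of melanin synthesis, rose from 0.777 ± 0.82 to 47.0 ± 5.5 CPM (log2 fold change 5.96, SE 0.87, adjusted p = 0.00337). TYRP1 rose to 193.5 ± 70.6 CPM and GPNMB to 42.7 ± 33.5 CPM. The summed level of the list was 152 ± 71.7 CPM in control and 930.5 ± 318 CPM in OVB organoids (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). PMEL, a melanosome protein, was at 47.1 ± 42.8 and 222 ± 53.4 CPM and missed the threshold (adjusted p = 0.051), and its exons overlap those of CDK2 on the other strand. MITF, a regulator of pigment cells, rose by 1.96 on the log2 scale (adjusted p = 0.00937). In the list of the retinal pigment epithelium and visual cycle 10 of 21 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.814 with an estimated correlation). RPE65, the visual cycle isomerase, rose by 7.10 (SE 0.97, adjusted p = 0.00289) and CLDN19 by 3.80 (SE 0.66), whereas LRAT fell by 2.23. That list's call was lost without OVB replicate 3 (adjusted p = 0.0831), and the call of TYRP1 without control replicate 2 (adjusted p = 0.0522).

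Photoreceptor genes and some eye field factors were higher in OVB replicate 3 than in the other OVB libraries. In OVB replicate 3 against the mean log2 CPM of the other OVB libraries, 24 of 28 photoreceptor, 13 of 21 eye field and optic vesicle, 13 of 19 retinal progenitor, 10 of 17 amacrine, horizontal and bipolar and 7 of 19 ganglion cell genes were higher. SIX6, an eye field factor, was at 0.634, 0.896 and 32.1 CPM in OVB replicates 1, 2 and 3 against 0.613 ± 0.607 CPM in control organoids, and missed the threshold (adjusted p = 0.0811). RAX, another eye field factor, was at 6.78, 4.26 and 62.4 CPM against 0.771 ± 0.516 CPM and rose (log2 fold change 5.00, SE 1.21, adjusted p = 0.0171). CRX, the photoreceptor factor, was at 1.48, 0.529 and 19.3 CPM against 0.1 ± 0.091 CPM (log2 fold change 6.20, SE 1.73, adjusted p = 0.0272). Of 28 tested photoreceptor genes 13 rose and 1 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.814 with an estimated correlation), and that call was lost without OVB replicate 3 (adjusted p = 0.0981). PDC and GNGT1 rose by 6.06 and 5.62, GNGT1 in a locus shared with TFPI2 on the other strand. GNGT1 was at 0.247, 0.338 and 14.3 CPM in OVB replicates 1, 2 and 3. Its log2 fold change was 1.54 without OVB replicate 3. The summed photoreceptor level did not separate the groups, at 904 ± 40.2 and 933 ± 238 CPM (n = 3 each, exact two-sided permutation p = 1). CRX, PDC and GNGT1 stood at 0.1, 0.0324 and 0.103 CPM in control organoids, so other members made up nearly all of that sum. The sum therefore does not show how these genes changed. The calls of RAX and CRX were lost without any 1 of the control libraries (adjusted p from 0.0518 to 0.0692 and from 0.078 to 0.0906). That of PDC was lost without control replicate 1 or 2 (adjusted p = 0.073 and 0.0737), and that of GNGT1 without any 1 control library or OVB replicate 3 (adjusted p from 0.1 to 0.138).

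**Figure D2:**
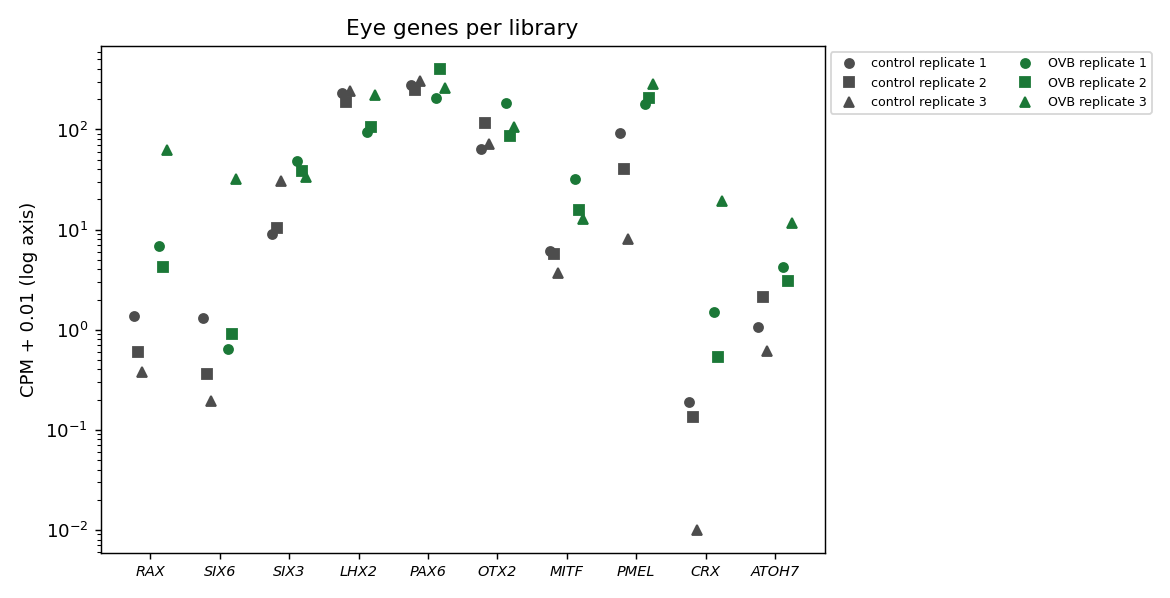
Points give CPM plus 0.01 on a log axis for 10 genes of the eye in each of the 6 libraries, grey for control and green for OVB organoids, with the replicate number as the shape. RAX and SIX6 stand at 62.4 and 32.1 CPM in OVB replicate 3.

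Other eye lists went both ways, except for the ganglion cell list, which was lower. Of 21 eye field and optic vesicle factors 3 rose and 2 fell, alike adjusted over the list alone (camera adjusted p = 0.661). HMX1 rose by 3.81 and LHX9 fell by 2.33. PAX6 was at 277 ± 30.0 and 291 ± 100.0 CPM (adjusted p = 0.839), LHX2 at 222 ± 29.9 and 140.0 ± 70.6 CPM (adjusted p = 0.146), OTX2 at 84.2 ± 28.9 and 125 ± 51.3 CPM (adjusted p = 0.214) and SIX3 at 16.7 ± 12.2 and 39.8 ± 7.36 CPM (adjusted p = 0.0711). Of 19 retinal progenitor genes 1 rose and 5 fell, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.471). ATOH7, needed for ganglion cells, rose by 2.35, while the Notch target HES5 fell by 1.49 and SFRP1 by 1.32. The retinal ganglion cell list had 0 of 19 members higher and 7 lower, alike adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.527 with an estimated correlation). Its members POU4F1, NEFL and SLC17A6 fell by 3.62, 2.18 and 2.15, and NEFL and SLC17A6 also serve many other neurons. POU4F1 was at 1.84, 7.19 and 1.20 CPM in control replicates 1, 2 and 3. Its log2 fold change was -2.46 without control replicate 2. Of 17 amacrine, horizontal and bipolar cell genes 8 rose and 4 fell, alike adjusted over the list alone (camera adjusted p = 0.404), with TRPM1, GAD1 and BHLHE22 higher by 4.67, 3.91 and 3.36. GAD1 is also on the GABAergic list and BHLHE22 on the cortical excitatory neuron list. TRPM1 ranked the libraries in the same order as the melanin gene TYR. These rises therefore do not single out amacrine, horizontal or bipolar cells. The calls of HMX1 and BHLHE22 were lost without any 1 of the control libraries (adjusted p from 0.0571 to 0.0925 and from 0.0895 to 0.0981). That of ATOH7 was lost without control replicate 1 or 3 (adjusted p = 0.112 and 0.0881), that of POU4F1 without control replicate 2 or OVB replicate 2 (adjusted p = 0.0517 and 0.0556), that of SLC17A6 without control replicate 1 (adjusted p = 0.0528) and that of TRPM1 without control replicate 2 (adjusted p = 0.0758).

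Surface epithelium genes were lower in OVB replicate 3 than in the other OVB libraries, and lens genes went both ways. In the cornea and surface epithelium list 10 of 15 rose and 0 fell, or 11 and 0 adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.814 with an estimated correlation). Its summed level was 303.5, 1288 and 62.4 CPM in OVB replicates 1, 2 and 3 against 50.6 ± 32.9 CPM in control organoids (n = 3, exact two-sided permutation p = 0.2). CDH1, the epithelial cadherin, rose by 5.01 (SE 0.74, adjusted p = 0.0035). GRHL2 was at 5.94, 25.4 and 0.0577 CPM, and its call was lost without any 1 control library, OVB replicate 1 or OVB replicate 2 (adjusted p from 0.0665 to 0.126). Of 10 tested lens genes 4 rose and 0 fell, alike adjusted over the list alone (camera adjusted p = 0.354). CRYAB, a small heat shock protein of lens and other tissues, rose by 8.13 and was at 2.01, 41.5 and 106 CPM in OVB replicates 1, 2 and 3. HSF4 rose by 3.90 and was at 12.1, 7.77 and 23.1 CPM. FOXE3, a lens factor, was at 0.159, 12.8 and 0.25 CPM, and its call was lost without any 1 of the control libraries (adjusted p from 0.0976 to 0.109).

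**Figure D3:**
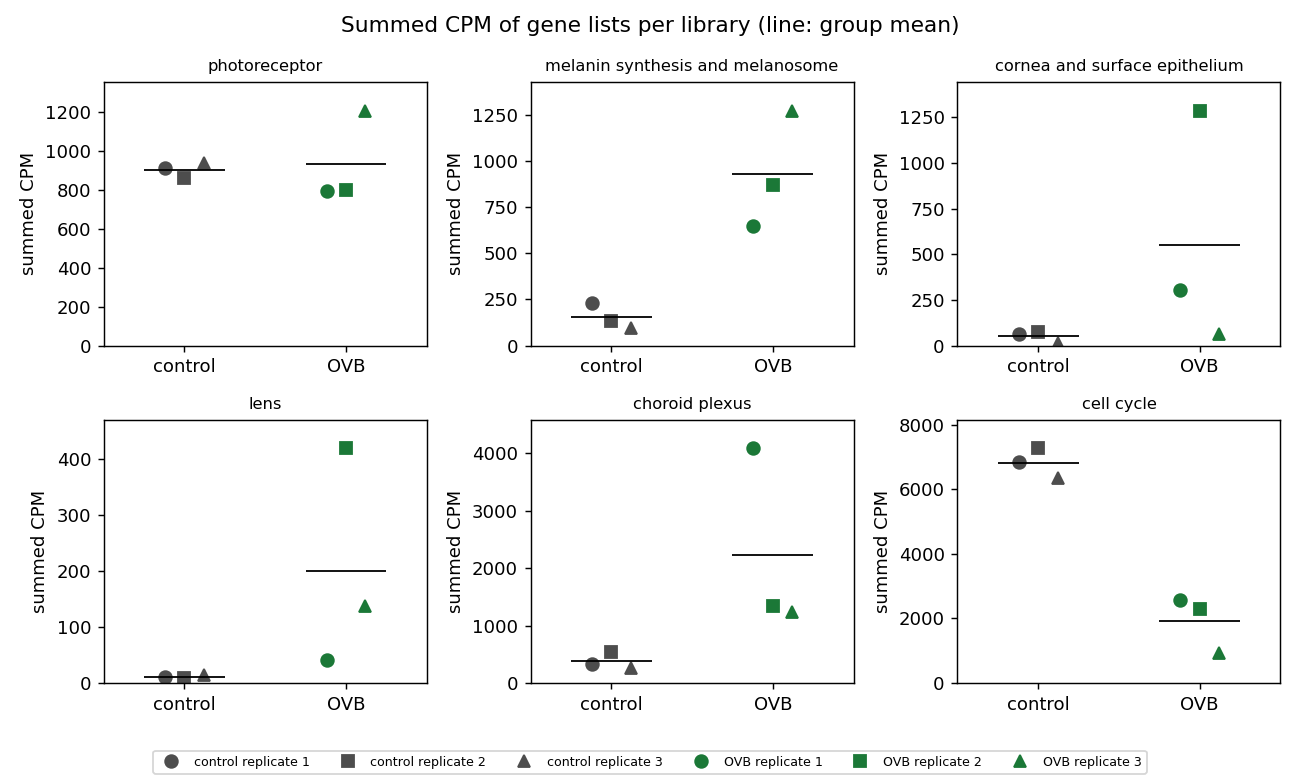
Points give the summed CPM of 6 gene lists in each library and lines the group means, with grey for control and green for OVB organoids. The cell cycle list fell from a mean of 6832 to 1925 CPM, while the epithelium list ranged from 62.4 to 1288 CPM among OVB libraries. The photoreceptor sum comes mostly from members other than CRX, PDC and GNGT1. In the choroid plexus sum, TTR alone had a mean of 1416 of 2224 CPM in OVB organoids.

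Cortical neuron genes were higher in OVB organoids. Of 20 cortical excitatory neuron genes 12 rose and 1 fell, alike adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.527 with an estimated correlation). NEUROD2 rose from 1.35 ± 0.454 to 178 ± 67.5 CPM (log2 fold change 7.05, SE 0.42, adjusted p = 0.000887), NEUROD6 by 7.96 (SE 0.91) and SLA by 6.20 (SE 0.64). Of 40 neuronal and synaptic genes 19 rose and 6 fell, or 19 and 7 adjusted over the list alone (camera adjusted p = 0.0471, adjusted p = 0.814 with an estimated correlation). The NMDA receptor genes GRIN2B and GRIN1 rose by 4.06 and 2.97 and RBFOX3 by 3.17. This call was lost without control replicate 1, control replicate 2, OVB replicate 1 or OVB replicate 3 (adjusted p = 0.0567, 0.215, 0.0891 and 0.0986). Of 19 GABAergic genes 4 rose and 1 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.691), with CALB2 and NPY higher by 3.07 and 2.80. The GABAergic sum was 675, 521 and 209 CPM in OVB replicates 1, 2 and 3 against 227 ± 81.1 CPM in control organoids. In OVB replicate 3, 17 of the 19 were lower than in the mean log2 CPM of the other OVB libraries. Of 23 dorsal forebrain progenitor genes 4 rose and 7 fell, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.404). Its summed level was lower, at 5759 ± 143 CPM in control and 4181 ± 370 CPM in OVB organoids (SD, n = 3 each, exact two-sided permutation p = 0.1). The members with the largest changes were HOPX, TNC and FAM107A, markers of outer radial glia, which rose by 5.25, 3.57 and 3.11. The diencephalon and hypothalamus list was lower, with 1 of 17 higher and 7 lower, alike adjusted over the list alone (camera adjusted p = 0.0189, adjusted p = 0.527 with an estimated correlation). Its members FOXB1 and OLIG3 fell by 4.79 and 3.85. OLIG3 was at 1.31, 5.12 and 0.491 CPM in control replicates 1, 2 and 3, and its log2 fold change was -2.49 without control replicate 2. In the midbrain and hindbrain list 1 of 14 rose, EN2, and 0 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.989). The call of NPY was lost without control replicate 1, control replicate 2 or OVB replicate 2 (adjusted p from 0.0557 to 0.0859). That of OLIG3 was lost without control replicate 1, control replicate 2, OVB replicate 2 or OVB replicate 3 (adjusted p from 0.0639 to 0.0965), that of EN2 without control replicate 1 or 2 (adjusted p = 0.113 and 0.103), and that of TNC without control replicate 2 (adjusted p = 0.0629).

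Proliferation genes and most stem cell genes were lower in OVB organoids. Of 35 cell cycle genes 0 rose and 30 fell, or 0 and 32 adjusted over the list alone (camera adjusted p = 2.67e-11, adjusted p = 0.814 with an estimated correlation). The summed level was 2571, 2287 and 917 CPM in OVB replicates 1, 2 and 3 against 6832 ± 466 CPM in control organoids (SD, n = 3). All 35 were lower in OVB replicate 3 than in the mean log2 CPM of the other OVB libraries. BIRC5, HMMR and GINS2 fell by 2.82, 2.63 and 2.56, though exons of GINS2 overlap GSE1 on the other strand. Of 11 replication-dependent histone genes 0 rose and 6 fell, alike adjusted over the list alone (camera adjusted p = 0.0115, adjusted p = 0.814 with an estimated correlation), with HIST2H2AC lower by 2.73. Of 9 tested pluripotency genes 2 rose and 7 fell, alike adjusted over the list alone (camera adjusted p = 0.0214, adjusted p = 0.814 with an estimated correlation), and that call was lost without OVB replicate 3 (adjusted p = 0.0746). All 9 were lower in OVB replicate 3 than in the mean of the other OVB libraries. The 2 that rose, chosen after their values were seen, were NANOG, from 6.17 ± 0.513 to 10.2 ± 1.28 CPM (log2 fold change 0.72, SE 0.20, adjusted p = 0.0289), and POU5F1, from 0.175 ± 0.0715 to 0.577 ± 0.101 CPM (log2 fold change 1.69, SE 0.42, adjusted p = 0.0179). Exons of POU5F1, with 132 counts in all, overlap TCF19 on the other strand, with 5991. The call of NANOG was lost without any 1 library but OVB replicate 3 (adjusted p from 0.0768 to 0.131), and that of POU5F1 without control replicate 1, control replicate 2, OVB replicate 1 or OVB replicate 2 (adjusted p from 0.0541 to 0.0784).

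Choroid plexus genes were higher in OVB organoids. In that list 12 of 16 rose and 0 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00241, adjusted p = 0.814 with an estimated correlation). CLIC6 rose by 6.87 (SE 0.99) and HTR2C by 6.08 (SE 1.14). TTR, the transthyretin gene held also by the pigment epithelium and endoderm lists, was at 2882, 601 and 766 CPM against 34.6 ± 56.5 CPM, and its call was lost without any 1 library but control replicate 2 (adjusted p from 0.0669 to 0.124). In the muscle list 7 of 13 rose and 0 fell, alike adjusted over the list alone (camera adjusted p = 0.0506), with MYOG at 1.01 ± 0.197 CPM and TNNT1 higher by 3.77. That list was called higher without control replicate 1, control replicate 2, OVB replicate 1 or OVB replicate 3 (adjusted p = 0.0216, 0.0255, 0.0114 and 0.0425), with RLE scaling (adjusted p = 0.0441) and with the replicate number as a block (adjusted p = 0.0249). It was not called with an estimated correlation (adjusted p = 0.814). Astrocyte genes had 4 of 15 higher and 1 lower, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.251), among them SPARCL1, higher by 3.34. Oligodendrocyte genes had 1 of 10 higher and 3 lower, alike adjusted over the list alone (camera adjusted p = 0.696), and neural crest genes 1 of 14 and 5, alike adjusted over the list alone (camera adjusted p = 0.229). The neural crest list was called lower without control replicate 3 (adjusted p = 0.0204) and with the replicate number as a block (adjusted p = 0.0468). It was not called over all libraries with an estimated correlation (adjusted p = 0.814). SOX10, a factor of the oligodendrocyte lineage and the neural crest, was at 47.4 ± 54.2 and 3.14 ± 2.87 CPM, its exons overlap POLR2F on the other strand, and its call was lost without control replicate 1, control replicate 2, OVB replicate 1 or OVB replicate 3 (adjusted p from 0.0735 to 0.114). Mesenchyme genes had 5 of 24 higher and 1 lower, alike adjusted over the list alone (camera adjusted p = 0.523). Endothelium and microglia genes had 2 of 8 higher, KDR by 5.02 and CSF1R by 3.82, and 0 lower, alike adjusted over the list alone (camera adjusted p = 0.471). Endoderm genes had 2 of 6 higher and 0 lower, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.939). Motile cilium genes had 1 of 20 higher and 0 lower, or 0 and 0 adjusted over the list alone, and primary cilium genes 5 of 30 and 7, alike adjusted over the list alone (camera adjusted p = 0.354 for each). All 20 motile cilium genes were lower in OVB replicate 3 than in the mean log2 CPM of the other OVB libraries, and without OVB replicate 3 the list was called higher (adjusted p = 0.0289). Over all libraries the motile cilium list was not called with an estimated correlation either (adjusted p = 0.955).

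Lists of cell state went both ways. Of 19 hypoxia and glycolysis genes 5 rose and 3 fell, alike adjusted over the list alone (camera adjusted p = 0.711), with the largest changes in PFKP, NDRG1 and VEGFA, higher by 2.42, 2.02 and 1.94. The summed level went the other way, at 5648 ± 777 CPM in control and 3226 ± 881 CPM in OVB organoids (SD, n = 3 each, exact two-sided permutation p = 0.1). Abundant members weigh most in such a sum, and the median log2 fold change of the list was 0.27. Of 16 stress genes 2 rose and 2 fell, alike adjusted over the list alone (camera adjusted p = 0.55), with TRIB3 higher by 1.87. Of 17 immediate early genes 7 rose and 2 fell, alike adjusted over the list alone (camera adjusted p = 0.354). FOSB stood at 1.37, 26.2 and 1.63 CPM in the OVB libraries, and its call was lost without any 1 of the control libraries (adjusted p from 0.0785 to 0.0885). Of 19 retinoic acid pathway genes 3 rose and 3 fell, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.85), and the retinoid enzyme ALDH1A1 was at 13.9, 439 and 18.5 CPM, its call lost without any 1 control library or OVB replicate 2 (adjusted p from 0.0636 to 0.118).

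At an adjusted p below 0.05, the authors' deposited table had 5793 genes higher and 6696 lower in OVB organoids. All 21718 genes tested here were in the authors' deposited table, and 8767 of the 9134 genes called here were called there with the same sign, 0 with the opposite sign. Both sets of calls come from the same counts and are not independent.

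Leaving out control replicate 1 lowered the higher and lower genes to 1997 and 2453, and leaving out control replicate 2 lowered them to 2371 and 2696. With library totals alone 77.2% of calls were higher, against 52.0% with TMM scaling, and the median log2 fold change of tested genes shifted by 0.39. With upper quartile scaling 64.8% were higher and the shift was 0.18. Of 95 named calls, 51 were kept without any 1 library.

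In some lists that were not called, the summaries differed in sign. The median and mean log2 fold change were -0.10 and 0.44 for retinal progenitor, -0.37 and 0.09 for dorsal forebrain progenitor, and -0.22 and 0.01 for stress genes, all tested as lower. They were 0.17 and -0.40 for oligodendrocyte genes, tested as lower, and -0.18 and -0.03 for mesenchyme genes, tested as higher. With library totals alone the medians of the retinal progenitor, dorsal forebrain progenitor, stress, mesenchyme and primary cilium lists turned positive, and no list that was called changed the sign of its median under another scaling.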

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

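The correction for GC content and gene length was chosen after seeing the data. Of 1725 values of named genes under an alternative, 1435 kept their side of the threshold, 271 were no longer past it and 19 came past it. A sign change with a call in either fit occurred in 0. Sign changes with a call in neither fit were not counted apart from the 1435. Mitochondrial genes had 0 counts, so leaving them out was not run as a setting. With library totals alone 7865 genes were higher and 2327 lower, and testing against a 2-fold change left 1493 genes. Leaving out 1 library gave 1997 to 6227 higher genes, 2453 to 5973 lower genes and 3236 to 7350 genes changed at least 2-fold. With an estimated correlation 0 lists were called higher and 0 lower, against 7 and 5. Leaving out 1 library gave 6 to 7 lists higher and 4 to 6 lower. With fry 6 lists were called higher and 4 lower. It lost the photoreceptor, cornea and surface epithelium, neuronal and histone lists (fry adjusted p = 0.101, 0.136, 0.0809 and 0.089). It gained the amacrine, horizontal and bipolar list and the muscle list, both higher (fry adjusted p = 0.0123 and 0.0262). Requiring a 2-fold change in both tables left 5431 shared calls. The cause was not tested for the scaling, library, correlation and fry settings, whereas the tests against 2-fold ask for a larger change by construction.

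The replicate numbers did not pair the libraries, since deviations of same-numbered libraries correlated at -0.12, 0.079 and -0.0073. With the replicate number as a block 3154 genes were higher and 3058 lower, and 2960 were higher with the block and the GC content and gene length correction. The block uses up residual degrees of freedom, and the cause was not tested.

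In simulations at this depth and spread, with 100 genes set to each size of change, most 2-fold changes went uncalled. That share does not carry over to a comparison with far more calls. Genes past no threshold are still not shown to be alike.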

Other observations

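All tests in this part except that of ribosomal protein pseudogenes and that of other splits were chosen after the results were seen. Regulators of developmental timing differed. Of 9 early RNA-binding and oncofetal genes 9 fell (median log2 fold change -2.85), and of 8 late progenitor and glial genes 6 rose and 0 fell (median 3.85). Both lists hold genes already named above for their change, such as LIN28A and HOPX, so they are no independent evidence and no list test is given. Age at collection is not given, so no explanation was tested.

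Cytosolic ribosomal protein genes were lower in OVB organoids, with 62 of 77 past the threshold and lower and 1 past it and higher. Their median log2 fold change was -1.23, and -0.86 with library totals alone. The list was added after the results were seen, so its list test is no independent evidence. That test was adjusted over the lists added in this part alone (camera adjusted p = 6.4e-15, adjusted p = 0.283 with an estimated correlation). Reads moving to pseudogenes do not account for the lower levels, since genes and pseudogenes summed to 0.42 times the control level. These sums were 37049, 40788 and 79624 CPM in OVB replicates 1, 2 and 3, so OVB replicate 3 was the nearest to the control libraries, at 101470 to 146780 CPM. Gene length here is that of all annotated exons of a gene, and GC content covers all its listed transcripts. A trend with the length of the transcripts actually expressed was therefore not tested. A trend with annotated exon length and GC content across all genes is argued against as the whole cause. Its correction moved other genes by a median of 0.15, and the median of the 76 ribosomal protein genes with a GC value went from -1.23 to -1.17 (SD of the members 0.46 with the correction), with 56 past the threshold and lower against 61 without it. A trend with abundance, alone or together with gene length and GC content, stays open. Random lists of other genes, matched as closely as possible, had a median of -0.88. Abundant genes of like annotated exon length thus fell too. As these were 0.65 log2 CPM less abundant, they cannot exclude a trend with abundance. The run, as read from the library codes, stays open as well, since 0 such runs hold both groups. It cannot be told apart from a difference between the organoids.

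OVB replicate 3 stood apart from OVB replicates 1 and 2, with correlations of log2 CPM across genes of 0.945 and 0.943 against 0.981 between those. A mislabelled control library is argued against. Of 12434 genes called between control replicates 1 and 2 and OVB replicates 1 and 2, 81.7% differed in the same direction between OVB replicate 3 and control replicate 3. The photoreceptor list had a median difference of 1.30 and the cornea and surface epithelium list -3.60, and these lists were chosen after the results were seen. A smaller share of 1 main tissue that raises every other tissue alike is argued against only if that tissue did not hold the surface epithelium. If it did, these lists cannot decide. No biological explanation was tested, because the labels divide the OVB libraries no further.

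Genes with many counts were absent from the authors' deposited table, among them the lens crystallin CRYAA, with 17194 counts, 252 CPM in OVB replicate 2 and 0.0176 and 0.461 CPM in the others, and the cone gene PDE6H, at 26.4 CPM in OVB replicate 3, both chosen after their values were seen. The outlier filter of DESeq2 is argued against as the cause, since only 35.5% of 107 genes without a p-value in DESeq2 were absent and 69 were listed there. A filter on counts may account for it. Among 102 rules scanned, at least 6 counts in at least 3 libraries separated listed from absent genes with 0 of 41320 genes misplaced, so genes of 1 or 2 libraries are in neither table of calls.

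The 9134 called genes of the real grouping compare with 0 in the highest of the other splits of the 6 libraries, and 10 splits are too few for a share under 0.05.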
